A study of Mus musculus with 9 samples.

How the data were processed

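RNA from 9 samples of primary mouse B cells (3 untreated, 3 after 1 h and 3 after 2 h of anti-IgM) had been labelled with biotin and hybridized to Illumina bead arrays. The deposited table used here holds a linear intensity for each of 45281 probes on each array, and the software that made it is not given in the sources used here. Judging from the values, the deposited intensities had been background-subtracted, since 31.8% were below 0, and normalized between arrays, since the upper quartiles differed by 0.35% at most. A second deposited table, of non-normalized signals, has 9 value columns whose names match no label of a single sample, so these 9 columns were not assigned to samples and not used here. It gives no detection p-values. The planned background correction and normalization with neqc were therefore not possible, and the deposited intensities were taken as log2 of the intensity plus 50.

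A probe counted as above noise on an array when its intensity exceeded the upper 0.05 tail of the noise, taken from the values below 0 mirrored around 0. This threshold, with a median of 6.44, stood in for the planned detection p-value. Probes above noise on at least 3 of the 9 arrays were kept (20983). Of all probes, 34885 had 1 gene symbol, 18 several and 10378 none in the platform's annotation. Of those with 1 symbol, 34807 matched a gene of the RefSeq annotation of GRCm38 and 0 symbols changed. For each gene the probe with the highest mean was used, which left 14640 features, of which 11104 had a gene name and 3536 (24.2%) were unnamed probes. Of 114 named genes with several kept probes, the probes differed in sign for 19 at 1 h, 18 at 2 h and 47 between the times. Ighm and Cd79a, which the rule for named genes lists, had no kept probe and are not analysed here.

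Groups followed the deposited labels throughout. A mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 6 residual degrees of freedom and a median residual standard deviation of 0.202 on the log2 scale. The comparisons were 1 h with untreated, 2 h with untreated, 2 h with 1 h, and any change across the 3 groups (moderated F-test). All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 14640 features, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are limma's moderated standard errors. Time classes combined the 3 pairwise calls, and the overlap of the 1 h and 2 h calls was set beside 100 simulations of unchanged groups that shared the untreated arrays.

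A total of 31 gene lists were written before the data were examined, for signalling, growth, stress and the cell types that a spleen preparation can hold. Lists of at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. A score per array is the mean log2 level of a list's members after each gene's mean over the 9 arrays was subtracted. Genes were named by a rule set before the data were examined: per comparison up to 10 rises and 10 falls past the threshold (6 and 6 between the times), per list up to 4 members past the threshold or else the 2 with the highest mean, and a fixed set of B cell, early response and reference genes. As no gene passed, the list members and the fixed set were used, and any other gene is marked as named after its values were seen.

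The scripts were tested on simulated data with the spread of these arrays and 200 changed genes in 5 runs of the 2 h comparison. Changes of 2-fold were recovered for 69.8% of genes and of 4-fold for 94.8%, with 8.6 false calls per run on average. The changed genes were drawn at random, with noise independent between arrays that all followed their label. These shares do not hold for genes with a large spread between arrays of a label, such as Egr1 and Ccl4. An absence of calls therefore does not show that large changes were absent. Alternatives set before the data were examined covered background correction, normalization, the filter on dim probes, the choice of probe, a replicate block, the variance model, array weights, the threshold, the arrays in the fit, the set test and leaving out each array in turn. Added after seeing the data were offsets of 16 and 100, a block for hemoglobin-rich arrays, and fits without the 3 arrays whose nearest arrays carry other labels or without 2 of them (untreated replicate 2 and 2 h replicate 2). The spread between arrays of a label sets the precision, and no sequencing depth applies.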

Results

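Transcript levels were measured in B cells purified from the spleens of 8-week-old C57BL/6 mice. Cells were left untreated or had their antigen receptor (BCR) crosslinked with an F(ab')2 antibody to IgM at 2.5 µg/ml, and RNA was hybridized to Illumina bead arrays. The sample labels give 3 groups of 3 arrays each: untreated, anti-IgM for 1 h and anti-IgM for 2 h. The series description gives 3 h in place of these times, and the labels were followed. The protocol also names IL-4 at 5 ng/ml and CD40 ligand at 200 ng/ml "as indicated", and the labels do not say which arrays received them. Each array held 45281 probes, with a median intensity of 3.76 to 3.77 and 19088 to 19112 probes above noise. No pair of arrays held identical values (0 pairs). Nothing in the labels says that the 3 arrays of a group came from separate mice or cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. Camera's p-values at the preset correlation compare a list's genes with the other genes and treat them as nearly independent. They do not measure how far the arrays of a label disagree on a list. The spread between arrays of a label and their number limit the precision of each value.

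Genes known to respond early to receptor stimulation separated the arrays sharply, but not along the labels. Egr1, an immediate-early transcription factor gene (chromosome 18, 34861207 to 34864956, GRCm38), had intensities of 1054, 8548 and 876 on untreated replicates 1, 2 and 3. Its intensities were 10635, 4017 and 12904 on the 1 h replicates and 6918, 1279 and 7312 on the 2 h replicates. The growth regulator gene Myc (chromosome 15, 61985341 to 61990361) gave 57.0, 798 and 70.0 untreated, 841, 583 and 816 at 1 h, and 876, 56.4 and 801 at 2 h. The chemokine gene Ccl4 (chromosome 11, 83648624 to 83664683) gave 289, 11981 and 526 untreated, 11402, 19817 and 14441 at 1 h, and 14820, 304 and 14396 at 2 h. Of 4 genes chosen after their values were seen, Irf4 and Nop58 divided the untreated and 2 h arrays in the direction of Egr1, and Klf2 and Txnip in the opposite one. Klf2, a transcription factor gene known for its high level in resting lymphocytes, had 841, 129 and 862 untreated, 340, 31 and 249 at 1 h, and 115, 818 and 146 at 2 h. Over all 14640 features, untreated replicate 2 was nearest to 2 h replicate 1 (Pearson r across genes 0.986) and 2 h replicate 3 (0.982). The array labelled 2 h replicate 2 was nearest to untreated replicates 1 (0.994) and 3 (0.992). The array labelled 1 h replicate 2 was nearest to untreated replicate 2 (0.978) and 2 h replicate 1 (0.970), and its r with 1 h replicate 1 was 0.945. Genes are not independent replicates, and no p-value is given for these correlations. Every comparison keeps the deposited labels.

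**Figure D1:**
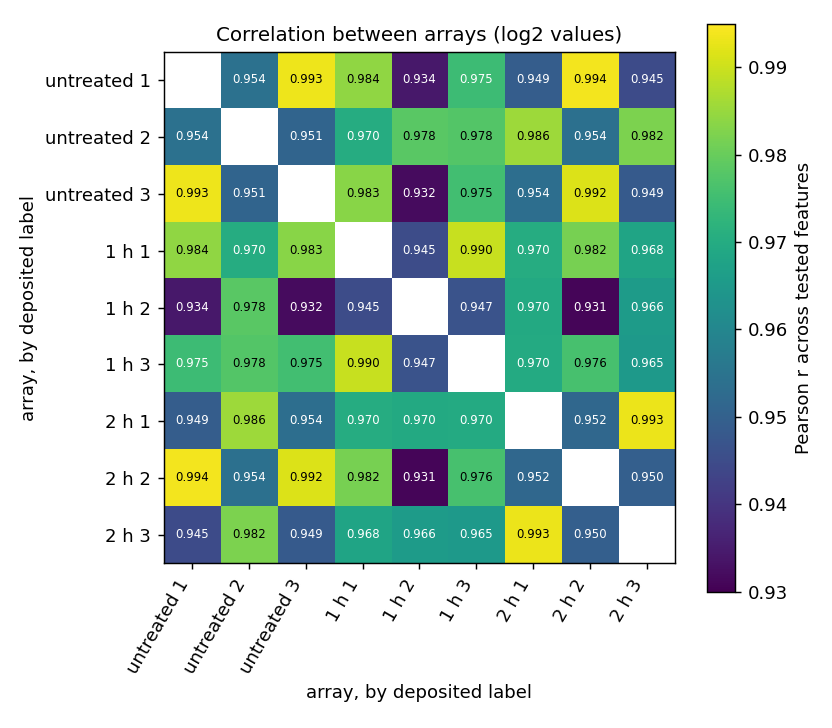
Pearson correlation between each pair of the 9 arrays over 14640 log2 features, with arrays named by deposited label on both axes and color for r. Untreated 2 lies closest to 2 h replicates 1 and 3 (0.986 and 0.982), and 2 h replicate 2 lies closest to untreated replicates 1 and 3 (0.994 and 0.992).

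**Figure D2:**
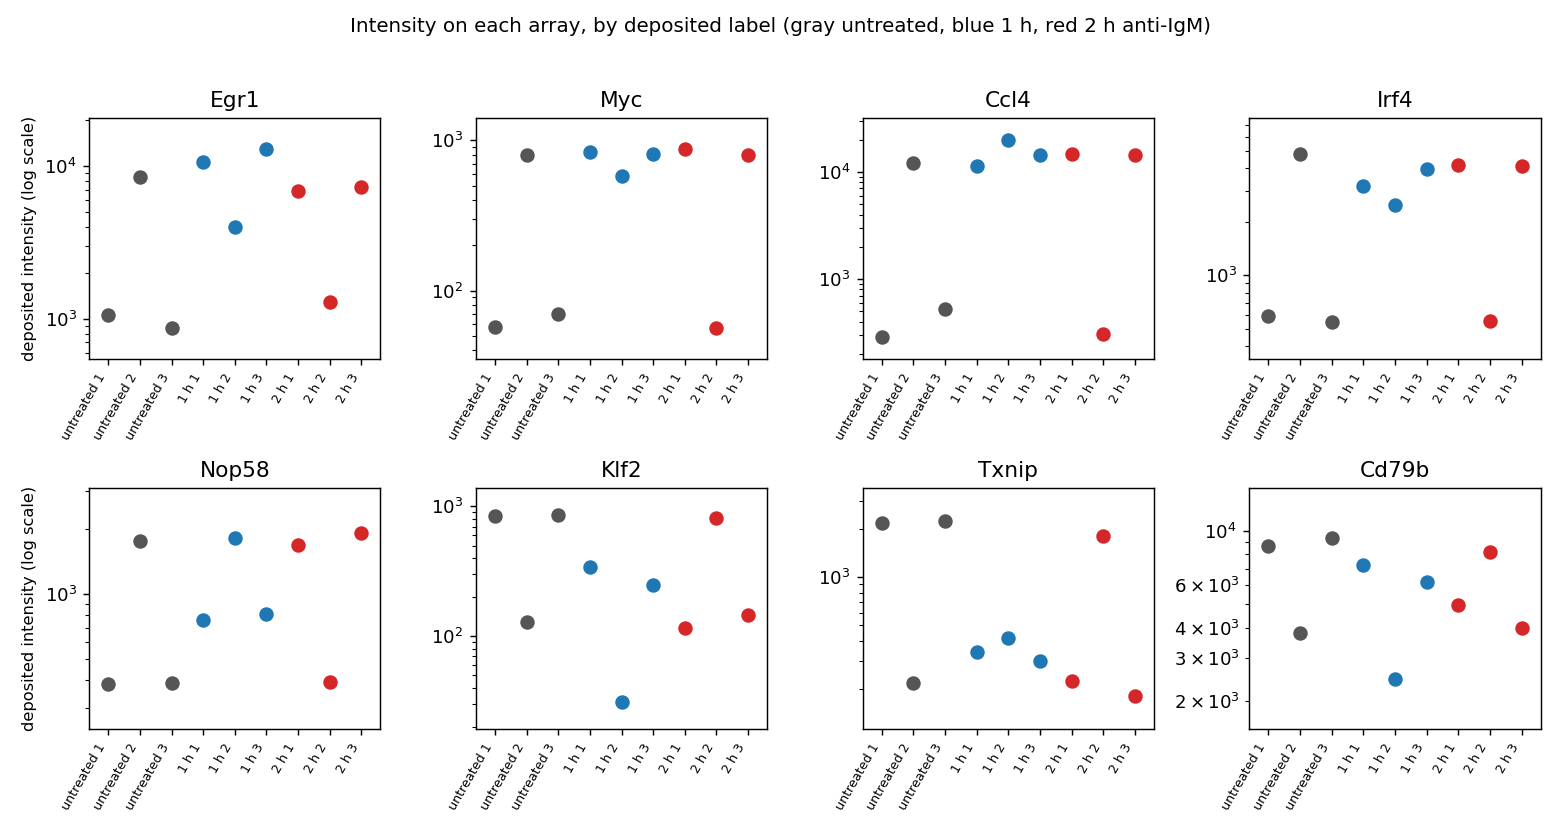
Deposited intensity (log scale) of 8 genes on each array, with 1 point per array, in gray for untreated, blue for 1 h and red for 2 h. Egr1 stands at 8548 on untreated replicate 2 and at 1279 on 2 h replicate 2, away from the other arrays with the same label.

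The comparison of 1 h with untreated asks which transcripts move within the first hour after receptor crosslinking. Immediate-early transcription factors were the list with the largest mean difference: 23 of 25 measured members were higher and the mean log2 difference was 0.98. The list rose by camera (adjusted p = 5.3e-13), and the call was lost with an estimated correlation (adjusted p = 0.824 with an estimated correlation). Its score per array was -0.89, 0.39 and -0.89 untreated against 0.76, -0.12 and 0.91 at 1 h. Among members, log2 differences were 2.00 ± 0.99 for Egr1, 1.64 ± 0.97 for Egr3, 1.40 ± 0.61 for Fos and 1.83 ± 0.99 for Myc (SE, n = 3 arrays per group), all with adjusted p = 1. The early activation marker Cd69 had 1.69 ± 0.68. The chemokine genes Ccl4 and Ccl3, which encode attractants of T cells and myeloid cells, had 3.49 ± 1.69 and 2.86 ± 1.48. Without 1 array these ranged from 1.42 to 3.03 for Egr1, 1.04 to 2.63 for Egr3, 1.04 to 1.98 for Fos, 1.30 to 2.80 for Myc, 1.30 to 2.36 for Cd69, 2.50 to 5.08 for Ccl4 and 2.02 to 4.17 for Ccl3, highest without 1 h replicate 2 for Fos and without untreated replicate 2 for the others.

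The NF-kappaB list and the list of MAPK phosphatases and Sprouty-type inhibitors also rose by camera at 1 h. Members of the NF-kappaB feedback and target list were higher for 19 of 24 (mean log2 difference 0.34, adjusted p = 0.00862), with Bcl2a1d at 0.73 ± 0.56. The MAPK inhibitor list was higher for 10 of 16 (0.37, adjusted p = 0.0195), with the ERK phosphatase gene Dusp2 at 2.06 ± 1.06. Both calls were lost with an estimated correlation (adjusted p = 0.846 with an estimated correlation for each). The NF-kappaB call was also lost without untreated replicate 1 (0.20, adjusted p = 0.226), untreated replicate 3 (0.20, adjusted p = 0.314) or 1 h replicate 3 (0.28, adjusted p = 0.112). The MAPK call was lost without the same arrays, at 0.30, 0.23 and 0.29 (adjusted p = 0.114, 0.419 and 0.103). Leaving out untreated replicate 2 moved the NF-kappaB mean to 0.62 and the MAPK mean to 0.58. Without 1 array, Bcl2a1d ranged from 0.47 to 1.22 and Dusp2 from 1.48 to 3.18, both highest without untreated replicate 2. Another named member of each list, Cd83 and Rasa1, ranged from -0.07 to 0.36 and from -0.24 to 0.29. RGS and SOCS inhibitors were higher for 6 of 17 (adjusted p = 0.88) and inhibitory coreceptors for 5 of 16 (adjusted p = 0.204).

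The list of cholesterol synthesis genes and LXR targets rose by camera at 1 h: 16 of 20 measured members were higher and 4 lower, with a mean log2 difference of 0.27 (adjusted p = 3.34e-07, and adjusted p = 0.667 with an estimated correlation). Adjusted over the list alone, 2 of 20 members rose, against 0 over all genes tested. These were Msmo1, a sterol demethylation enzyme gene (0.69 ± 0.14, adjusted p = 0.0183 over the list and 1 over all genes), and Stard4, a cholesterol carrier gene (0.63 ± 0.14, with the same adjusted p-values), both named after their values were seen. Msmo1 intensities were 872, 828 and 728 untreated and 1387, 1454 and 1184 at 1 h. The squalene epoxidase gene Sqle had 0.56 ± 0.27 and the farnesyl diphosphate synthase gene Fdps 0.30 ± 0.19, with probes of Fdps that differed in sign. Their differences were 0.31 and 0.07 without 1 h replicate 2. Without 1 h replicate 2, the list mean was 0.14 (adjusted p = 0.00536), and without the 3 arrays labelled replicate 2, a set chosen after seeing the data, the call was lost (0.16, adjusted p = 0.0515).

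Growth and stress lists also passed camera at 1 h, with values that turned on single arrays. Ribosome biogenesis genes were higher for 31 of 34 (mean log2 difference 0.27, adjusted p = 0.0128) and translation initiation and tRNA synthetase genes for 22 of 26 (0.20, adjusted p = 0.0128). Unfolded protein and amino acid stress genes were higher for 19 of 23 (0.31, adjusted p = 0.0012), and chaperones for 14 of 18 (0.16, adjusted p = 0.0407). The list of E proteins, Id proteins and B lineage regulators was lower for 16 of 19 (-0.22, adjusted p = 0.00398). With an estimated correlation, the adjusted p-values were 0.851, 0.851, 0.846, 0.851 and 0.846. Without 1 h replicate 2, the means were -0.16, -0.10, 0.04, -0.03 and 0.01, in the same order, and no call was left (adjusted p = 0.338, 0.0581, 0.879, 0.981 and 0.981). The ribosome biogenesis and translation calls were also lost without untreated replicate 1 (0.03 and 0.14) or untreated replicate 3 (0.06 and 0.12), and the chaperone call without untreated replicate 3 (0.09). With array weights the translation, stress, chaperone and E protein calls were lost (adjusted p = 0.386, 0.34, 0.434 and 0.386), and so they were without the 3 arrays labelled replicate 2, a set chosen after seeing the data (adjusted p = 0.679, 0.538, 0.303 and 0.544). The chaperone call was also lost with no filter on dim probes (adjusted p = 0.354), an offset of 16, also chosen after seeing the data (adjusted p = 0.0729), or only the 6 arrays of the 2 groups (adjusted p = 0.0558). Leaving out untreated replicate 2 moved ribosome biogenesis to 0.72, translation to 0.33 and chaperones to 0.28. Named members had differences of 0.62 ± 0.69 for Gnl3, a nucleolar GTPase gene, 0.67 ± 0.52 for the helicase gene Eif4a1, 0.46 ± 0.28 for Atf4, 0.53 ± 0.51 for Hspa9 and -0.30 ± 0.32 for the B cell coactivator gene Pou2af1. Without 1 array these ranged from 0.26 to 1.31, 0.34 to 1.23, 0.28 to 0.68, 0.06 to 0.97 and -0.52 to 0.10, in the same order. Other named members of these lists moved less or against their list. Ranges without 1 array were -0.08 to 0.21 for Npm1 (ribosome biogenesis) and 0.12 to 0.50 for Eif5 (translation). They were -0.43 to -0.06 for Xbp1 (stress), 0.07 to 0.23 for Hspa8 (chaperones) and -0.23 to -0.03 for Id3. On 1 h replicate 2, the amino acid response genes Asns and Chac1, named after their values were seen, had intensities of 1359 and 1786, against 82.1 to 300 and 85.3 to 324 on the other 8 arrays. Cd79b, a chain of the antigen receptor, had -0.49 ± 0.50 and intensities of 7250, 2450 and 6131 at 1 h against 8660, 3791 and 9360 untreated. It had -0.02 without 1 h replicate 2 and -0.91 without untreated replicate 2.

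For single genes at 1 h, limma called 0 of 14640 features. At an unadjusted p under 0.05 there were 190 features, where 732 would be given by chance, and the smallest adjusted p was 1. With array weights, 1 gene passed: Impact, a regulator of the amino acid sensor kinase GCN2, named after its values were seen, at a log2 difference of 1.19 (adjusted p = 0.0484). Without untreated replicate 2, 1 h replicate 2 and 2 h replicate 2, a set chosen after seeing the data from the correlations between arrays, 577 genes rose and 496 fell. Because those arrays were chosen from the same values, that choice narrows the spread within groups and its p-values are too small to serve as a test of the treatment.

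The comparison of 2 h with untreated asks what the response has become after a further hour. Genes of ribosome biogenesis were higher for 32 of 34 measured members, with a mean log2 difference of 0.44, and the list rose by camera (adjusted p = 0.00348). The call was lost with an estimated correlation (adjusted p = 0.878 with an estimated correlation). Scores per array were -0.71, 0.67 and -0.66 untreated against 0.64, -0.67 and 0.63 at 2 h. Nop58, a nucleolar gene for small nucleolar ribonucleoproteins, had intensities of 383, 1752 and 391 untreated and 1692, 395 and 1919 at 2 h. Gnl3 had a log2 difference of 0.44 ± 0.69 (adjusted p = 0.915), with 0.08 without untreated replicate 1 and 1.13 without untreated replicate 2. Npm1, another named member, ranged from -0.18 to 0.06 without 1 array. The list call was lost without untreated replicate 1 (0.20, adjusted p = 0.441), untreated replicate 3 (0.22, adjusted p = 0.161), 2 h replicate 1 (0.22, adjusted p = 0.2) or 2 h replicate 3 (0.22, adjusted p = 0.318). The list mean was 0.89 without untreated replicate 2 and 0.87 without 2 h replicate 2.

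Of the other groups known to respond to the antigen receptor, none passed at 2 h with the settings used for the values here, and some passed with others. The immediate-early list was higher for 21 of 25 members (mean log2 difference 0.41, adjusted p = 0.14) and the NF-kappaB list for 20 of 24 (0.29, adjusted p = 0.113). Chaperones were higher for 13 of 18 (0.26, adjusted p = 0.0762). The MAPK inhibitor list had a mean of 0.16, translation 0.07, unfolded protein and amino acid stress 0.05, E proteins and B lineage regulators -0.16 and cholesterol synthesis -0.09. With array weights, camera called the immediate-early (1.07, adjusted p = 9.33e-05), NF-kappaB (0.72, adjusted p = 0.000385), chaperone (0.45, adjusted p = 0.0118), MAPK inhibitor (0.45, adjusted p = 0.021) and translation lists (0.25, adjusted p = 0.027). Without untreated replicate 2, the immediate-early (0.84, adjusted p = 0.000216), NF-kappaB (0.57, adjusted p = 0.000126), chaperone (0.37, adjusted p = 0.0207) and MAPK inhibitor lists (0.38, adjusted p = 0.0299) passed. Without 2 h replicate 2, the immediate-early (0.81), NF-kappaB (0.55) and chaperone lists (0.40) passed, with adjusted p = 0.00551, 0.00551 and 0.00962. With the mean of a gene's probes, the immediate-early (0.38), NF-kappaB (0.32) and chaperone lists (0.25) passed, with adjusted p = 0.0494, 0.0494 and 0.0323, and with probes above noise on all 9 arrays chaperones did (0.32, adjusted p = 0.00314). The lowest means without 1 array were 0.19 for the immediate-early list and 0.15 for NF-kappaB. Log2 differences were 0.99 ± 0.99 for Egr1, 0.98 ± 0.99 for Myc, 0.66 ± 0.68 for Cd69, 1.67 ± 1.69 for Ccl4 and 1.77 ± 1.48 for Ccl3, each with adjusted p = 0.908. Without 1 array they ranged from 0.41 to 2.02 for Egr1, 0.44 to 2.00 for Myc, 0.27 to 1.32 for Cd69, 0.69 to 3.46 for Ccl4 and 0.93 to 3.36 for Ccl3, highest without untreated replicate 2 for Egr1 and Cd69 and without 2 h replicate 2 for Myc, Ccl4 and Ccl3. Cd79b had -0.31 ± 0.50 and intensities of 4943, 8160 and 3995, and ranged from -0.72 to -0.07 without 1 array. Ppp3r1, the regulatory subunit of calcineurin, had -0.41 ± 0.12 (adjusted p = 0.883). Adjusted over the list alone, 2 of 20 B cell surface and antigen presentation genes rose, against 0 over all genes tested: the tetraspanin gene Cd53 (0.73 ± 0.17) and the MHC class II gene H2-Aa (0.44 ± 0.10), both with adjusted p = 0.0276 over the list and 0.825 over all genes, named after their values were seen. That list as a whole had a mean of -0.07 (adjusted p = 0.996). The transcription factor gene Tcf3, an E protein, was not above noise on any of the 3 arrays at 2 h and is given no fold there.

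Limma called 0 of 14640 features between 2 h and untreated, with 727 at an unadjusted p under 0.05 and a smallest adjusted p of 0.825. With array weights 2191 genes rose and 2707 fell. The use of weights was set before the data were examined, but their values were estimated from these same arrays. They were lowest for 1 h replicate 2 (0.261), 2 h replicate 2 (0.308) and untreated replicate 2 (0.343). Such weights narrow the spread within groups, so the genes and lists called with them are no firm test of the treatment. Without these 3 arrays 2303 genes rose and 2785 fell, with the same reservation about their choice.

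Between 1 h and 2 h, the immediate-early list and the list of cholesterol synthesis genes and LXR targets fell by camera. The immediate-early list was lower for 20 of 25 members (mean log2 difference -0.57, adjusted p = 0.00242, and adjusted p = 0.942 with an estimated correlation), with Egr1 at -1.02 ± 0.99, Fos at -0.83 ± 0.61, Myc at -0.85 ± 0.99 and Cd69, from the activation list, at -1.04 ± 0.68. Without 1 array these 4 genes ranged from -1.53 to -0.21, -1.40 to -0.33, -1.39 to 0.17 and -1.47 to -0.47, each highest without 2 h replicate 2. This call was lost without 1 h replicate 1 (-0.45, adjusted p = 0.056), 1 h replicate 3 (-0.37, adjusted p = 0.0843) or 2 h replicate 2 (-0.17, adjusted p = 0.405), and without 1 h replicate 2 the mean was -0.89. The cholesterol list was lower for 16 of 20 (-0.36, adjusted p = 1.45e-06, and adjusted p = 0.735 with an estimated correlation). Its scores per array were 0.08, 0.46 and 0.09 at 1 h and -0.11, -0.18 and -0.16 at 2 h, so each array at 2 h was below each at 1 h, and without 1 h replicate 2 the mean was -0.23 (adjusted p = 0.000293). Adjusted over the list alone, 3 of 20 members fell, against 0 over all genes: Msmo1 (-0.73 ± 0.14, adjusted p = 0.0119), Stard4 (-0.68 ± 0.14, adjusted p = 0.0119) and Insig1 (-0.80 ± 0.18, adjusted p = 0.0127), a feedback inhibitor of sterol synthesis whose probes differed in sign, all named after their values were seen. Over all genes their adjusted p-values were 0.393, 0.397 and 0.409. Sqle had -0.65 ± 0.27 (adjusted p = 0.71) and Fdps -0.51 ± 0.19 (adjusted p = 0.639), and without 1 h replicate 2 they had -0.40 and -0.28.

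The other called lists of the 1 h comparison did not pass between 1 h and 2 h with the settings used for the values here. Mean log2 differences were -0.05 for NF-kappaB, -0.21 for MAPK inhibitors, 0.07 for E proteins and B lineage regulators, 0.17 for ribosome biogenesis, -0.13 for translation, 0.10 for chaperones and -0.26 for unfolded protein and amino acid stress, whose adjusted p was 0.167. Ribosome biogenesis and chaperones passed with array weights (0.82, adjusted p = 6.49e-09, and 0.34, adjusted p = 0.0125) and without 1 h replicate 2 (0.59, adjusted p = 0.000146, and 0.29, adjusted p = 0.0427), and ribosome biogenesis without 2 h replicate 2 (0.60, adjusted p = 0.000476). Translation passed at -0.30 without 1 h replicate 1 (adjusted p = 0.0212) and at 0.17 without 1 h replicate 2 (adjusted p = 0.0257). Stress genes passed without 1 h replicate 1 (-0.39), 1 h replicate 3 (-0.40) or 2 h replicate 3 (-0.32), with adjusted p = 0.0212, 0.00401 and 0.0387, and with probes above noise on all 9 arrays (-0.29, adjusted p = 0.0404). Adjusted over their lists alone, Cd53 (0.80 ± 0.17), the cytokine gene Il12a (0.45 ± 0.10) and the cathepsin gene Ctss (1.01 ± 0.18), from the macrophage, monocyte and dendritic cell list, rose from 1 h to 2 h, with adjusted p = 0.0333, 0.0339 and 0.0092. These 3 genes were named after their values were seen. Over all genes the adjusted p was 0.409 for Cd53 and Il12a and 0.393 for Ctss. Limma called 0 of 14640 features between the 2 times, with 1001 at an unadjusted p under 0.05 and a smallest adjusted p of 0.393. Array weights gave 25 genes (20 higher at 2 h and 5 lower), and leaving out the 3 arrays named above gave 1765 that rose and 2000 that fell.

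Across the 3 groups in 1 test, limma called 0 features, with 639 at an unadjusted p under 0.05 and a smallest adjusted p of 0.729. Array weights gave 3462 genes and the 6 arrays left without the 3 named above gave 5136. With no gene called, each time class (transient, progressive, held and late) held 0 genes, and 0 genes were called at both 1 h and 2 h. The log2 differences at 1 h and 2 h correlated across genes with r = 0.51, where simulated unchanged groups sharing the same untreated arrays gave 0.499, with covariances of 0.0273 and 0.0295. In the 6 arrays, r was 0.654 against 0.502 simulated and the covariance 0.111 against 0.00937. There 443 genes rose and 417 fell at both times, where the simulated groups shared 0.53 calls on average and independent lists would share 90.8 and 94.4. The simulated value leaves out any effects and the independent lists leave out the shared untreated arrays, which can give part of the excess.

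Quiescence genes, cytokines and nutrient genes had differences that did not pass at either time with the settings used for the values here. At 1 h and 2 h, mean log2 differences were -0.20 and -0.23 for quiescence, KLF2 and FOXO targets, 0.47 and 0.37 for cytokines and chemokines, 0.14 and 0.14 for lymphocyte activation markers, and 0.20 and 0.19 for polyamine, nucleotide and one-carbon synthesis. They were -0.18 and -0.22 for inhibitory coreceptors, -0.09 and -0.09 for receptor signalling components, -0.03 and -0.11 for the calcium and calcineurin-NFAT pathway, 0.05 and 0.12 for RGS and SOCS inhibitors and -0.19 at 1 h for B cell surface and antigen presentation genes. Glycolysis had 0.07 and -0.02, G1 cyclins and CDKs 0.02 and -0.10, DNA replication and mitosis -0.03 and -0.14, the BCL2 family -0.06 and -0.12, interferon-stimulated genes -0.13 and -0.17 and cytosolic ribosomal proteins -0.03 and 0.02. Camera adjusted p-values for these lists and for the cell type lists were 0.0827 to 0.993 at 1 h, 0.193 to 0.996 at 2 h and 0.167 to 0.997 between the times. At 1 h the median and the mean differed in sign for RGS and SOCS inhibitors (median -0.06), T cell markers (0.04) and plasma cell markers (0.03). At 2 h they did for stress genes, NK markers and marginal zone markers (median -0.03 each). Camera's direction differed from the sign of the mean for the RGS and SOCS, DNA replication, T cell, neutrophil, erythroid and plasma cell lists at 1 h and for B cell surface genes at 2 h. The reference genes Actb and Gapdh had 0.19 ± 0.18 and -0.04 ± 0.11 at 1 h and -0.09 ± 0.18 and -0.07 ± 0.11 at 2 h. Probes of Actb differed in sign at 1 h.

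Calls for these lists appeared with other settings or fewer arrays. Without 1 array, cytokines and chemokines ranged from 0.30 to 0.77 at 1 h and 0.18 to 0.72 at 2 h, activation markers from 0.05 to 0.31 and 0.04 to 0.32, and quiescence from -0.37 to -0.03 and -0.42 to -0.13. With array weights at 2 h, polyamine synthesis (0.46, adjusted p = 0.00943), quiescence (-0.53, adjusted p = 0.0141), DNA replication (-0.46, adjusted p = 0.000807) and interferon-stimulated genes (-0.33, adjusted p = 0.0437) passed. The same 4 lists passed at 2 h without untreated replicate 2, at 0.37, -0.41, -0.24 and -0.30 (adjusted p = 0.0404, 0.0253, 0.0415 and 0.0247). DNA replication also passed at 2 h without 2 h replicate 2 (-0.32, adjusted p = 0.00962) or untreated replicate 3 (-0.18, adjusted p = 0.0432), and at 1 h without untreated replicate 1 (0.11, adjusted p = 0.0195). At 1 h, polyamine synthesis passed at -0.18 without 1 h replicate 2 (adjusted p = 0.0236), and at 0.38, 0.38 and 0.40 without untreated replicate 2, 1 h replicate 1 or 1 h replicate 3 (adjusted p = 0.0202, 0.00293 and 0.000296). It also passed with probes above noise on all 9 arrays (0.22, adjusted p = 0.0226). Interferon-stimulated genes passed at 1 h without untreated replicate 2 (-0.27, adjusted p = 0.0202) or 1 h replicate 1 (-0.22, adjusted p = 0.0405). B cell surface genes did without untreated replicate 1 (-0.19, adjusted p = 0.048) or 1 h replicate 3 (-0.30, adjusted p = 0.00357), with normexp (-0.20, adjusted p = 0.0407) or with an added 32 and quantile normalization (-0.22, adjusted p = 0.0314), and inhibitory coreceptors without 1 h replicate 3 (-0.33, adjusted p = 0.0149). Between the times, array weights gave 0.42 for polyamine synthesis, -0.30 for quiescence, -0.29 for DNA replication and -0.22 for the calcium pathway (adjusted p = 0.0036, 0.0144, 0.00691 and 0.0471). Without 1 h replicate 2, polyamine synthesis, quiescence and the calcium pathway passed there at 0.38, -0.20 and -0.26 (adjusted p = 0.000753, 0.0181 and 0.00271). Without 1 h replicate 3, B cell surface genes, DNA replication and G1 cyclins passed at 0.23, -0.18 and -0.17 (adjusted p = 0.0325, 0.0152 and 0.0304), and DNA replication did at -0.29 without 2 h replicate 2 (adjusted p = 0.00702).

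**Figure D3:**
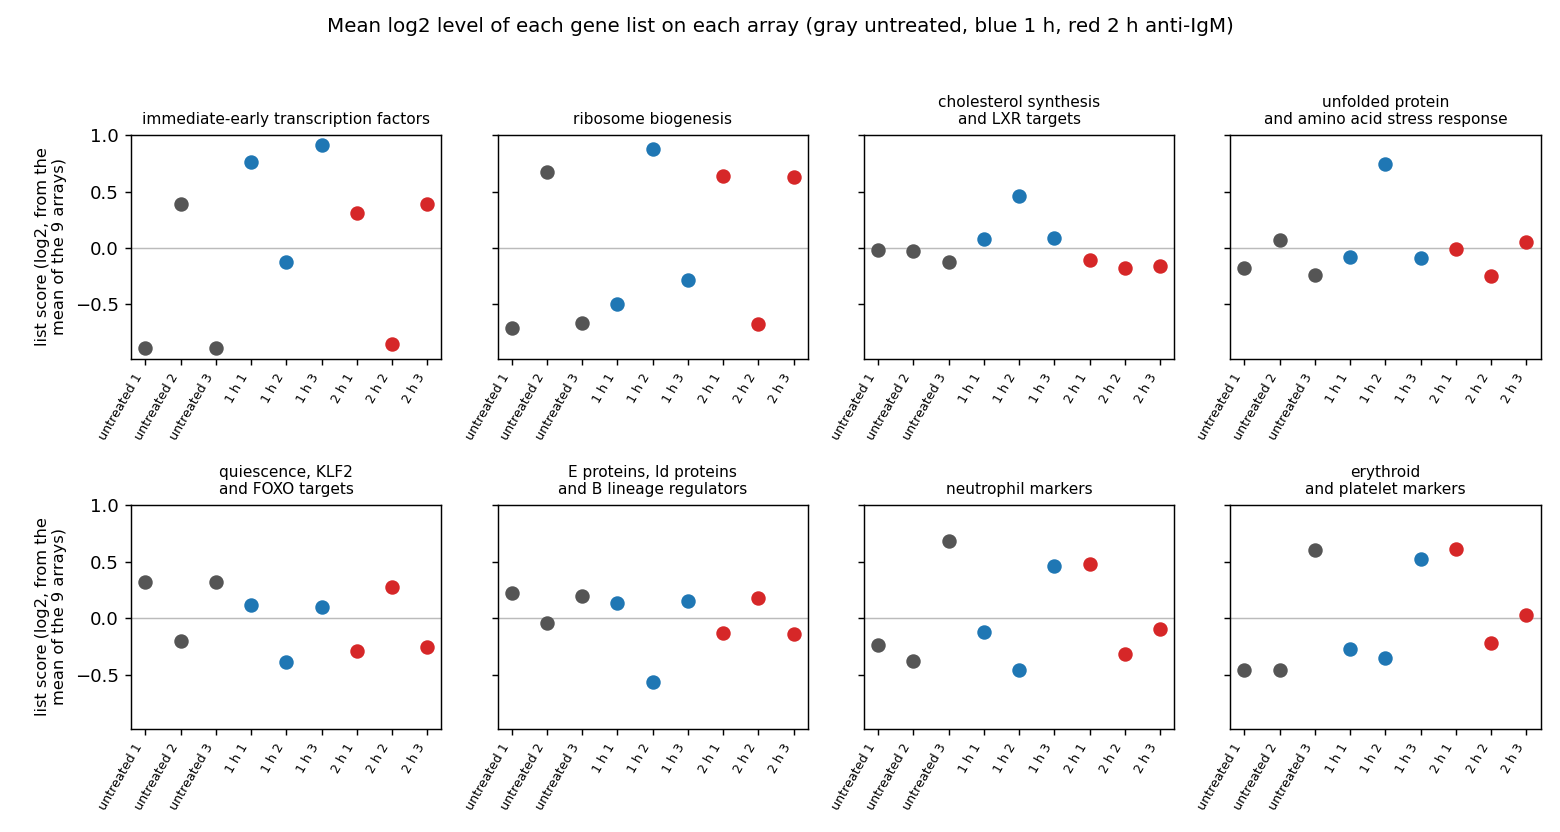
Score of 8 gene lists on each array (mean log2 level of the members, from the mean of the 9 arrays), with 1 point per array, in gray for untreated, blue for 1 h and red for 2 h. Ribosome biogenesis stands at 0.67 on untreated replicate 2 and at -0.67 on 2 h replicate 2, and the stress response list is highest on 1 h replicate 2, at 0.74.

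Lists of markers of other spleen cells passed camera in none of the 3 comparisons with the settings used for the values here, and 3 arrays stood apart in them. Mean log2 differences at 1 h and 2 h were -0.02 and -0.05 for T cells, 0.12 and 0.04 for NK cells, -0.12 and 0.07 for macrophages, monocytes and dendritic cells, -0.06 and 0.00 for neutrophils, 0.07 and 0.25 for erythroid cells and platelets, -0.04 and -0.13 for plasma cells, and -0.05 and 0.05 for marginal zone B cells. Between the times they were -0.03, -0.08, 0.19, 0.06, 0.18, -0.09 and 0.09, in the same order. Without untreated replicate 3, neutrophil markers passed at 1 h (0.27, adjusted p = 0.00336) and 2 h (0.33, adjusted p = 0.0088), NK markers at 1 h (0.20, adjusted p = 0.0077), and macrophage and erythroid markers at 2 h (0.25, adjusted p = 0.0088, and 0.60, adjusted p = 0.0432). Macrophage markers also passed at 1 h without untreated replicate 1 (-0.16), untreated replicate 2 (-0.25) or 1 h replicate 3 (-0.24), with adjusted p = 0.0125, 0.0361 and 0.00357. Between the times they passed without 1 h replicate 3 (0.31, adjusted p = 0.00401) or 2 h replicate 3 (0.23, adjusted p = 0.0418), and with the filter at the 1% noise tail (0.24, adjusted p = 0.0298). The alpha-globin gene Hba-a1 had an intensity of 2358 on untreated replicate 3, 2644 on 1 h replicate 3 and 2600 on 2 h replicate 1, against 65.9 to 325 on the other 6 arrays. The neutrophil gene S100a8 had 3091, 2582 and 2151 on those 3 arrays and 416 to 911 on the others. Each group holds 1 hemoglobin-rich array, so a block for them left the list means as they were. Within the hemoglobin-rich arrays, with 1 array per group and no error, the immediate-early list had 1.81 at 1 h, against 0.57 within the other 6. Ribosome biogenesis had 1.30 at 2 h within the hemoglobin-rich arrays and 0.00 within the others. The other 6 hold the 3 arrays nearest to other labels (the replicates 2), and the hemoglobin-rich arrays hold none of them. Without those 3, a choice made after seeing the data that leaves 1 array per group, the others had 1.65 and 1.34, near the values within the hemoglobin-rich arrays. From 1 h to 2 h the immediate-early list had -0.61 within the hemoglobin-rich arrays, -0.55 within the other 6 and -0.37 within these without the 3, and the cholesterol list had -0.20, -0.44 and -0.24. In the same order, values at 1 h were 0.74, 0.14 and 0.58 for NF-kappaB, 0.81, 0.15 and 0.63 for MAPK inhibitors, -0.05, -0.31 and -0.08 for E proteins and B lineage regulators, and 0.37, 0.21 and 0.21 for ribosome biogenesis. They were 0.10, 0.25 and -0.03 for translation, 0.10, 0.19 and 0.07 for chaperones, 0.15, 0.39 and 0.11 for stress genes and 0.21, 0.30 and 0.11 for the cholesterol list.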

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

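The splits of the arrays given here were chosen after the results were seen. The list of immediate-early transcription factors and the list of cholesterol synthesis genes and LXR targets stood out because the effect of anti-IgM at 1 h and at 2 h differed by the test of the difference itself. The immediate-early list had a mean log2 difference from untreated of 0.98 at 1 h and 0.41 at 2 h, and the difference between the times was -0.57 (camera, adjusted p = 0.00242). The cholesterol list had 0.27 and -0.09, and the difference between the times was -0.36 (adjusted p = 1.45e-06). With an estimated correlation, these adjusted p-values became 0.942 and 0.735, so both calls were lost. By camera, the immediate-early call was also lost without 2 h replicate 2 (-0.17, adjusted p = 0.405), an array nearest to untreated arrays. It was lost as well without 1 h replicate 1 (-0.45, adjusted p = 0.056) or 1 h replicate 3 (-0.37, adjusted p = 0.0843). The cholesterol call was kept without any 1 array. Of the 10 splits of the 6 arrays, 9 gave at least as many called lists as the real 2, and the highest other split gave 15. A design of 10 splits is too small for a share under 0.05. No explanation was tested for these differences.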

How the results depend on the processing

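Fits without 3 or 2 arrays, offsets of 16 and 100 and the hemoglobin block were chosen after seeing the data, and the other settings before. A result counts as reversed here when its direction (for lists, that of the test) turned and it was called on either side. By this measure, 160 of 162 differences of named genes and 84 of 93 list results never reversed over 31 settings. With no gene called in the main fit, a gene could seldom count as reversed, so this does not show stable directions. Over the settings, 180 single gene results changed sign without a call, and 3904 kept their sign and stayed uncalled. At 1 h, for example, Cd44 ranged from -0.21 to 0.93 and Mthfd2 from -0.38 to 1.12 without 1 array. Without 1 array, 44 of 93 list means changed sign, among them 4 of the 12 called. Genes called stayed at 0 in each comparison without any 1 array, and with the replicate block. The numbers were not taken to pair the arrays, since 3 of 9 pairs, all untreated with 1 h, correlated above 0.1 and 2 of 9 arrays matched their own number best. These correlations are of deviations from group means that include the arrays of replicate 2. They were not computed without those arrays, so whether the numbers pair the arrays stays open.

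Array weights gave 3462 genes across the groups, 1 at 1 h, 4898 at 2 h, 25 between the times, 1 transient and 23 late genes, and 5, 10 and 8 lists. The weights were estimated from the same values and were lowest for the 3 arrays of replicate 2, so these counts carry the same reservation as leaving them out. Without the 3 arrays whose nearest arrays carry other labels, counts were 5136, 1073, 5088 and 3765 genes, with 192 transient, 322 progressive, 559 held and 2732 late, 860 shared by both times, and 6, 14 and 14 lists. Cish turned to 0.84 at 1 h, Rasa1 to 0.413 at 2 h, and between the times E proteins turned to -0.279 and translation to 0.27. Without untreated replicate 2 and 2 h replicate 2, counts were 535, 99, 1314 and 0 genes, 99 held, 95 shared, and 13, 11 and 4 lists, and NF-kappaB between the times turned to 0.209. The median residual spread was 0.119 with 6 arrays and 0.163 with 7, against 0.202 with all. The covariance of the 1 h and 2 h differences was 0.111 with 6 arrays against 0.0273, and the cause of the higher counts was not tested.

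Called lists were 9 at 1 h, 1 at 2 h and 2 between the times. These became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. No filter, an offset of 16 and only the 6 arrays of 2 groups each kept 8 of the 9 at 1 h. At 2 h they were 2 with probes above noise on all 9 arrays and 4 with the mean of a gene's probes. The cause was not tested. Without 1 array they ranged from 5 to 12, 0 to 9 and 2 to 8. List means at 1 h then ranged from -0.35 to 0.015 for E proteins, -0.16 to 0.72 for ribosome biogenesis, -0.18 to 0.40 for polyamine synthesis, -0.10 to 0.37 for translation, -0.031 to 0.28 for chaperones and 0.035 to 0.45 for stress genes. Between the times translation ranged from -0.30 to 0.17. In each of these 7 the direction of the camera test turned without 1 h replicate 2, where the stress genes kept a mean above 0. Adjusted p over the alternatives ran from 3.98e-36 to 0.92 for the immediate-early list at 1 h, 2.2e-10 to 0.92 for cholesterol synthesis at 1 h, 7.89e-22 to 0.896 for ribosome biogenesis at 2 h, and 2.39e-07 to 0.969 and 5.03e-08 to 0.735 for immediate-early and cholesterol genes between the times.

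Not run were neqc with another offset, a block for slide, and neqc background correction before median scaling or loess, which were run on the log2 values in its place. The authors' normalized table was not an alternative, since its values were those used. Signal over background limits dim genes such as Tcf3, whose intensities were 7.4, 1.3 and 18.4 on the untreated arrays, against a noise threshold of 6.44.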

Other observations

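All tests in this part were chosen after the results were seen, and so were the genes named. Fosb, an AP-1 subunit gene, had intensities of 401 and 398 on 1 h replicates 1 and 3, 52.2 on untreated replicate 2, and 44.0 and 51.1 on 2 h replicates 1 and 3. On untreated replicates 1 and 3, 1 h replicate 2 and 2 h replicate 2 it had 13.9, 3.2, 0.4 and 3.6. Egr4, of the same early response family as Egr1, had 1230 and 1224 on 1 h replicates 1 and 3, 183 on 1 h replicate 2, 360 on untreated replicate 2, and 291 and 365 on 2 h replicates 1 and 3. The cyclin gene Ccnd2 had 285, 2186 and 279 on the untreated arrays, 488, 2135 and 610 at 1 h, and 1456, 421 and 1627 at 2 h. The transferrin receptor gene Tfrc had 408, 2475 and 463 untreated, 824, 3941 and 1018 at 1 h, and 2357, 394 and 2184 at 2 h. The spermidine synthase gene Srm had 107, 1194 and 130 untreated, 177, 1741 and 243 at 1 h, and 1087, 121 and 1123 at 2 h.

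Ets1, Btk and Ptpn6, picked for it, had the opposite division, and Pik3ap1 and Bcl10, from the receptor signalling list, did not. Pik3ap1 had 1295, 3990 and 1235 untreated and 3418, 1572 and 2929 at 2 h, and Bcl10 had 1274, 2527 and 1280 untreated and 2076, 1240 and 2218 at 2 h. Ets1, a lymphocyte transcription factor gene, had 1638, 712 and 1630 on the untreated arrays, 1372, 254 and 1614 at 1 h, and 532, 1572 and 495 at 2 h. The receptor kinase gene Btk had 2373, 1022 and 2177 untreated, 1858, 797 and 2086 at 1 h, and 822, 2214 and 844 at 2 h. The phosphatase gene Ptpn6, an inhibitor of receptor signals, had 3067, 1355 and 3089 untreated, 2095, 1668 and 2019 at 1 h, and 1187, 3013 and 1000.1 at 2 h. The lymphotactin gene Xcl1 had 3799 on 1 h replicate 2 and at most 475 on the other 8 arrays.

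The arrays labelled untreated replicate 2 and 2 h replicate 2 each resembled the other label: on a scale from the mean of untreated replicates 1 and 3 (0) to the mean of 2 h replicates 1 and 3 (1), over 1015 genes at least 2-fold apart, they had median positions of 0.896 (quartiles 0.736 to 1.04) and 0.0218 (quartiles -0.0562 to 0.106). Lists of T cell, NK cell, macrophage, neutrophil and erythroid or platelet markers were tested for RNA of other cell types. Of these 5 lists, 0 were higher on either array than on all of the other 7. The T cell and NK cell lists scored -0.14 and -0.12 on untreated replicate 2, and 0.01 and 0.07 on 2 h replicate 2. Both lists were highest on 1 h replicate 1 (0.15 and 0.13). The scores of the 2 arrays lie within the range of the other arrays, so RNA of T cells and NK cells stays open. The macrophage, neutrophil and erythroid or platelet lists were each highest on a hemoglobin-rich array. Those lists could hardly have passed, so RNA of those cells stays open. An exchange of names is a candidate explanation, as both partners are out of place and 6436 genes parted the 6 arrays without overlap by exchanged names, against 1635 by deposited names. Each gene without ties parts exactly 1 of the 10 possible splits, so equal shares would give each split 1 in 10 of the 14640 features. The 1635 are near that share and close to the highest of the 8 splits that follow neither naming (592 to 1571). The 6436 leave fewer genes for the other splits, so the 8 are no independent measure of chance. They are also too few for a share under 0.05, so whether some genes follow the deposited names stays open. An exchange of names cannot be told apart from cultures treated other than named, since both predict nearest arrays of the other label, as found for 2 of 2 arrays, and which array received which treatment stays open.

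The array labelled 1 h replicate 2 stood apart from 1 h replicates 1 and 3: on a scale from these (0) to 2 h replicates 1 and 3 (1), its median position was 1.01 over 461 genes (quartiles 0.694 to 1.29). An exchange of names with another of the 9 arrays is argued against, since 0 arrays of another label were nearest to 1 h replicates 1 and 3. For RNA of other cell types, 0 of 5 lists were above all other arrays, which include the hemoglobin-rich ones. T cell, macrophage and neutrophil markers scored -0.26, -0.34 and -0.46 on this array, the lowest of the 9, which argues against RNA of those cells. NK cell and erythroid markers scored -0.01 and -0.35, within the range of the other arrays, so RNA of those cells stays open. Cells further along the course from 1 h to 2 h are a candidate explanation for part of the pattern. Of the 461 genes, 50.8% lay past the 2 h end of the scale. No label gives a time after 2 h, so a later point of the course could not be tested. A single wrong name or an exchange with an outside sample needs no partner and stays open. Cells at the 2 h point are argued against for the list of cholesterol synthesis genes and LXR targets, whose position on the same scale was -1.73, with scores of 0.46 on this array, 0.08 and 0.09 on 1 h replicates 1 and 3 and -0.18 to -0.11 at 2 h. The stress list scored 0.74 against -0.25 to 0.05 at 2 h, Xcl1, Asns and Chac1 also stood above every array at 2 h, and what sets them apart was not tested.

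Untreated replicate 3, 1 h replicate 3 and 2 h replicate 1 were rich in hemoglobin transcripts. These 3 arrays were also the highest 3 of 9 for 16 of 31 neutrophil and macrophage genes, among them S100a8, Lyz1 and C1qb, where chance gives 0.369, and for 2 of 19 T cell and NK cell genes, where chance gives 0.226. Spleen cells other than B cells left by the purification may have contributed RNA to these arrays. A response to anti-IgM is argued against, because 1 of the 3 arrays is untreated. Purity of the B cells was not given in the sources used here, and each group holds 1 of these arrays.

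Other splits of the arrays were counted for each comparison with limma and camera, where limma called 0 genes. Unadjusted p-values under 0.05 numbered 639 across the groups, 190 at 1 h, 727 at 2 h and 1001 between the times, and limma with array weights called 3462, 1, 4898 and 25 genes. Every split reaches a real count of 0, so for genes the shares of splits below decide nothing about chance. Across the 3 groups, 100 of 100 drawn splits gave at least as many genes as the real 0, and the highest other gave 412. At 1 h, 10 of 10 splits gave as many genes as the real 0, the highest other also gave 0, and 6 of 10 gave as many lists as the real 9, with 15 as the highest. At 2 h, 10 of 10 gave as many genes as the real 0, and the highest other gave 2739. That split set untreated replicates 1 and 3 with 2 h replicate 2 against untreated replicate 2 with 2 h replicates 1 and 3, which points to a structure of the samples other than their labels. For lists at 2 h, 10 of 10 splits gave as many as the real 1, with 12 as the highest. Between the times, 10 of 10 gave as many genes as the real 0, and the highest other gave 473, with 1 h replicates 1 and 3 and 2 h replicate 2 against the other 3 arrays. With 10 splits no share under 0.05 can be had.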
